A study of Drosophila melanogaster with 4 samples.

How the data were processed

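The series describes ChIP-seq against Polycomb in wild-type Oregon-R embryos of 14 to 16 h, with 2 ChIP libraries and 2 input libraries. Per the labels' protocols, embryos were fixed with 1.8% formaldehyde and the crosslinked chromatin was precipitated with antibody. Bowtie 0.12.7 is named in the submitters' processing notes, without its settings. Per the file headers, positions are on FlyBase r5. The deposited files call their entries regions of significant enrichment. The program that called the regions, its threshold, its window and any minimum width are not given in the sources used here. Each ChIP library had a deposited list of its own, so replicates were compared list against list. The lists held no region with the same start and end, and were treated as separate libraries.

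Each deposited region carries a score in the authors' files, a positive decimal whose scale is not stated. It was used to rank, describe and filter regions within a list, to compare median scores between regions of the same list, and to correlate scores between the lists by rank and by value. The inputs had no values of their own here, so the enrichment over input could not be recomputed, and depth, read counts and background level per region were unknown. Intervals for shares of regions are exact (Clopper-Pearson) binomial intervals at 95% and cover counting error only.

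Groups and replicate numbers were taken from the sample titles. The experiment number in each ChIP sample's source name is the one in the name of the other ChIP sample's file. The recorded link between sample and file was used, which the descriptions of the inputs also follow. If the lists were exchanged, the replicate names would swap and the comparison between the lists would stay as it is.

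Regions were compared with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. A region counted as found in the other list when at least 1 base overlapped. Chance overlap came from 1000 circular shifts of the other list, with an independent random offset on each sequence, which keeps widths and spacing. Scores were correlated over one-to-one overlapping pairs, and shared and single-list regions were compared by median rank within a list, both with 100000 permutations. Region counts per sequence were tested against length with a chi-square statistic and 100000 simulated draws. Distances to the nearest region were compared with 10000 random placements of the same widths. Sequence lengths were read from the file headers. Seeds were fixed.

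The tests were tried on simulated data. Those of overlap and spacing used the 1189 regions of replicate 1 moved to other positions. The rank test used the replicate 1 scores in random order, and the chi-square test used counts drawn by sequence length. The overlap test, run with fewer shifts than on the data, called 1 of 20 unrelated lists. It called 20 of 20 lists that held only copies of 50% of the regions, each moved by 100 bases. The spacing test called 20 of 20 lists of paired regions and 0 of 20 uniform lists. Overlapping regions were merged in the uniform lists but not in the placements they were compared with. Merging lengthens distances and makes a call less likely, so the 0 of 20 does not give the rate of false calls. The rank test called 20 of 20 lists with some regions shifted by 20 percentiles and 1 of 20 without a shift. The chi-square test called 20 of 20 lists with an excess on 3R and 2 of 20 without one. Its lists drew every region independently, as the test itself assumes, so they do not show how often grouped regions would be called. The unrelated lists of the overlap test were circular shifts, as in the test itself.

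Tests, alternatives and the rule for naming regions were set before the data were examined, except where stated. The rule named the 10 highest-scoring and the 10 widest replicate 1 regions found in both lists, and the 5 highest-scoring regions of each replicate found in one list only. Added after the values were seen were the width classes, the joining of regions under 5 kb or 50 kb apart, the covered share per arm and every comparison of X, of unplaced sequence and of arm ends. Alternatives covered the overlap required (50% of both regions, or 50% of the shorter), the upper 50% of each list by score, merging of regions under 1 kb apart, the 5 large arms only, uniform placement as chance, the direction of the comparison, and lists of equal length. Placement relative to genes, 17 preset gene lists and sequence motifs had been planned for an annotation and genome of FlyBase r5. The gene table at hand is of Release 6, and coordinates were not converted, so these comparisons were not made.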

Results

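Chromatin bound by Polycomb was mapped by ChIP-seq in wild-type Drosophila melanogaster embryos of the Oregon-R strain, collected 14 to 16 h into development. Polycomb (Pc) is the chromodomain subunit of Polycomb repressive complex 1, which keeps developmental regulators such as the Hox genes silent. The series held 2 ChIP libraries (replicates 1 and 2) and 2 input libraries of genomic DNA. Each ChIP library had its own list of enriched regions with a score per region. Both lists were placed on FlyBase r5. Read counts per library were not given, so the sequencing depth behind each region was unknown. With 1 condition, 2 questions could be put to the lists: where Polycomb was enriched along the chromosomes, and how far the replicates agreed. The labels did not say whether the replicates came from separate embryo collections, so every p-value below compares positions or regions in these 2 libraries only. Regions were named by position and were not assigned to genes, since a gene annotation of FlyBase r5 was not used here.

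Polycomb covered similar amounts of the genome in both libraries, in broad blocks and many narrow sites. Replicate 1 listed 1189 regions over 8.62 Mb, and replicate 2 listed 1405 regions over 8.66 Mb. On the arms X, 2L, 2R, 3L and 3R and on chromosome 4, the lists covered 7.14% and 7.16% of the sequence. The median region was 2155 bases wide in replicate 1 and 2006 bases wide in replicate 2. The widest regions reached 227.2 kb and 189.4 kb. Regions of 10 kb or more numbered 207 in replicate 1 and 210 in replicate 2, and held 68.8% and 64.7% of the covered bases. Regions under 2 kb made up 45.0% and 49.8% of the lists but only 9.62% and 12.5% of the covered bases. No region was narrower than 1301 bases in replicate 1 or 1302 bases in replicate 2. Wider regions had higher scores (Spearman's rho across regions 0.77 in replicate 1 and 0.65 in replicate 2; regions are not independent replicates).

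**Figure D1:**
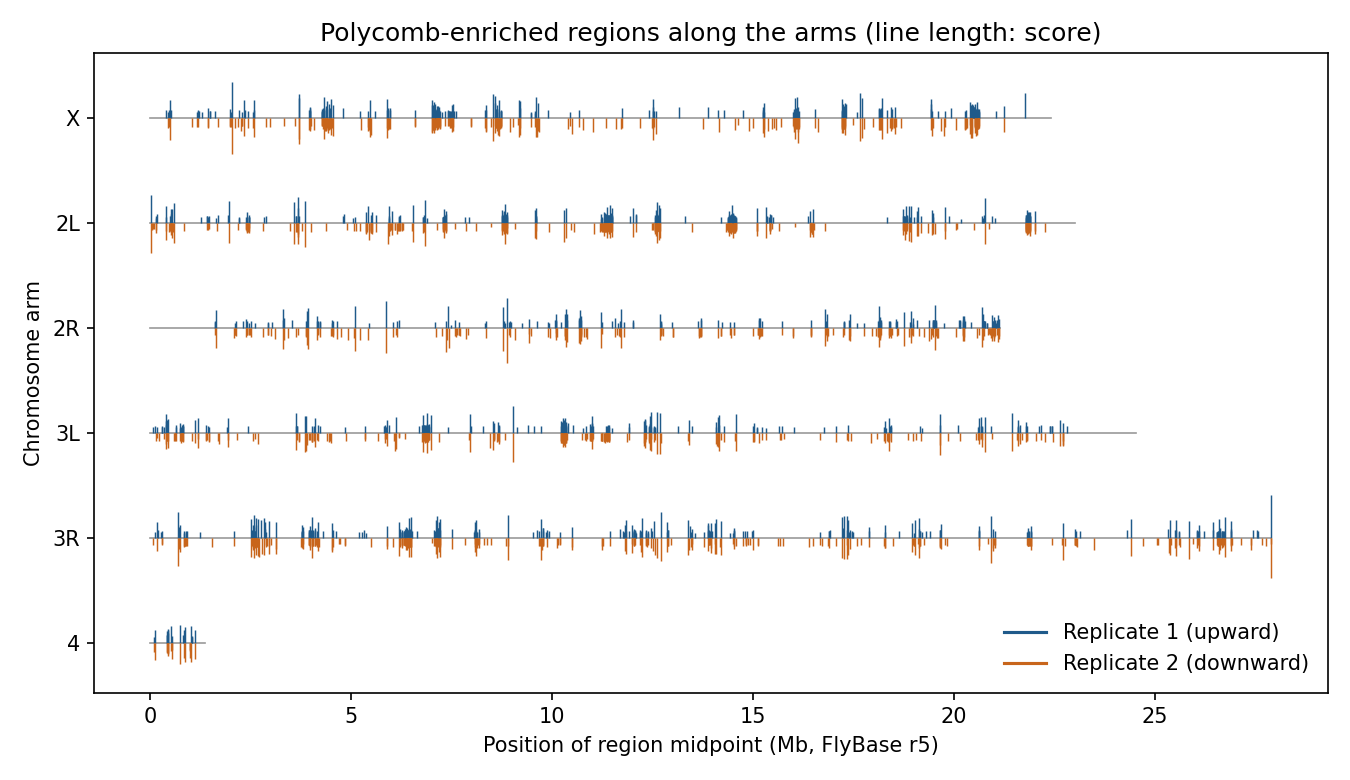
Positions of Polycomb-enriched regions on the arms X, 2L, 2R, 3L and 3R and on chromosome 4 (x axis, Mb of FlyBase r5), with replicate 1 drawn upward and replicate 2 downward and the length of each line in proportion to the region's score. The tallest line on the arms lies at the right end of 3R in both libraries (scores 3.05 and 2.85), and the regions fall into groups.

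The broad Polycomb blocks were found in both libraries, and the narrow regions mostly were not. All 207 regions of 10 kb or more in replicate 1 overlapped a replicate 2 region (exact binomial 95% interval 98.2 to 100%), as did all 210 in the other direction (98.3 to 100%). The other list covered 95.4% of the bases of these regions in replicate 1 and 97.0% in replicate 2. When 50% of both regions had to overlap, 90.3% and 88.6% of them were still found. Of the regions from 2 kb to under 10 kb, 378 of 447 in replicate 1 and 421 of 495 in replicate 2 were found in the other list. Of those under 2 kb, 184 of 535 (34.4%, 30.4 to 38.6%) and 222 of 700 (31.7%, 28.3 to 35.3%) were found. When 50% of both regions had to overlap, the shares were 55.5% and 49.1% from 2 kb to under 10 kb, and 15.3% and 12.6% under 2 kb. The width classes were chosen after the values were seen, the intervals cover counting error only, and neighbouring regions are not independent. Sliding the other list around each chromosome gave 21.8% and 18.8% for the regions of 10 kb or more, and 8.53% and 8.20% for those under 2 kb, as means of 1000 circular shifts.

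**Figure D2:**
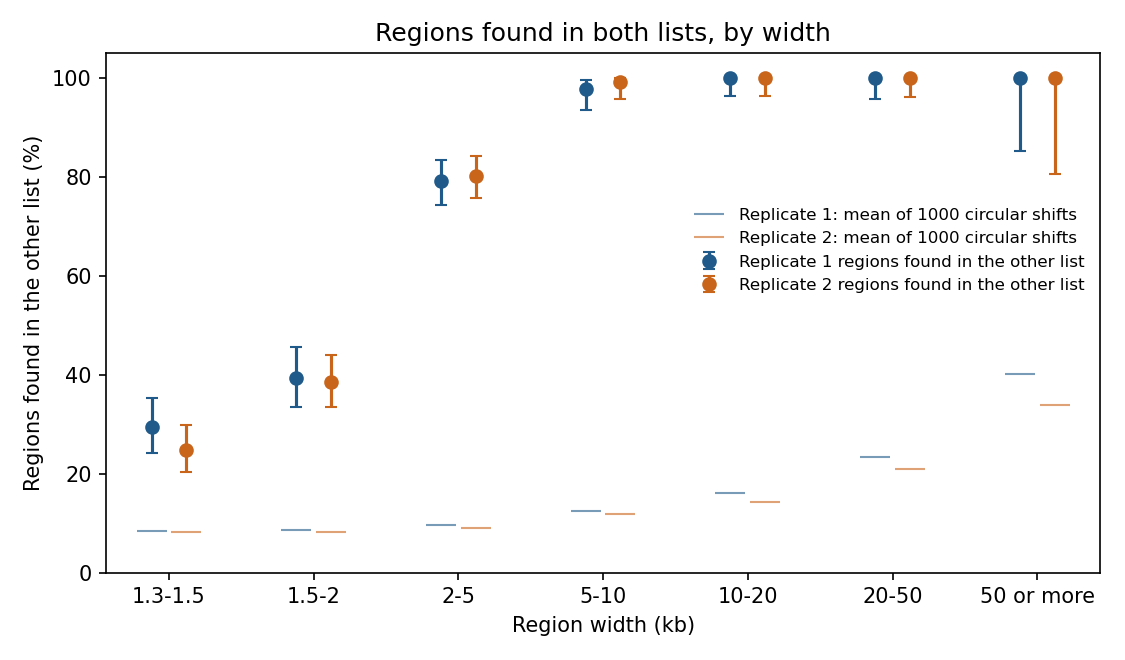
Share of regions found in the other list (y axis, %) by region width (x axis, kb) for replicates 1 and 2. Points are observed shares with exact binomial 95% intervals and dashes are means of 1000 circular shifts; from 10 kb upward every region was found, against 29.5% and 24.9% below 1.5 kb.

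Over all widths, 769 of the 1189 replicate 1 regions (64.7%, exact binomial 95% interval 61.9 to 67.4%) overlapped a replicate 2 region by at least 1 base. Circular shifts gave a mean of 11.7% and at most 23.3% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). In the other direction, 853 of 1405 regions (60.7%) were found. The shared sequence came to 7.20 Mb, which is 83.5% of the bases in replicate 1 and 83.1% of those in replicate 2. The Jaccard index of covered bases was 71.3%, against a mean of 3.91% and a highest value of 15.9% under the shifts (one-sided permutation p = 0.001). The share of replicate 1 regions was 43.5% when 50% of both regions had to overlap. More than 1 region of the other list was overlapped by 185 regions of replicate 1 and by 156 regions of replicate 2.

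The widest Polycomb region in either library lay on 3R, the arm that carries both Hox gene complexes. In replicate 1 it ran from 12587227 to 12814474 (227.2 kb, score 1.82). Replicate 2 covered 99.4% of it with 2 regions, the wider of which ran from 12625077 to 12814426 (189.4 kb, score 1.62). A second broad region lay just to its left, from 12484282 to 12583095 in replicate 1 (98.8 kb, score 1.20), of which replicate 2 covered 99.5%. Joining regions under 5 kb apart, a distance chosen after the values were seen, made this a block from 12482202 to 12814474 in replicate 1 (332.3 kb) and from 12482412 to 12814426 in replicate 2 (332.0 kb). The only wider block at that distance was also on 3R in both libraries. It ran from 2532987 to 2875271 in replicate 1 (342.3 kb in 16 regions) and from 2538690 to 2875323 in replicate 2 (336.6 kb in 22 regions). Its widest replicate 1 region, from 2693775 to 2796752, measured 103.0 kb and was covered to 98.2% by replicate 2.

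**Figure D3:**
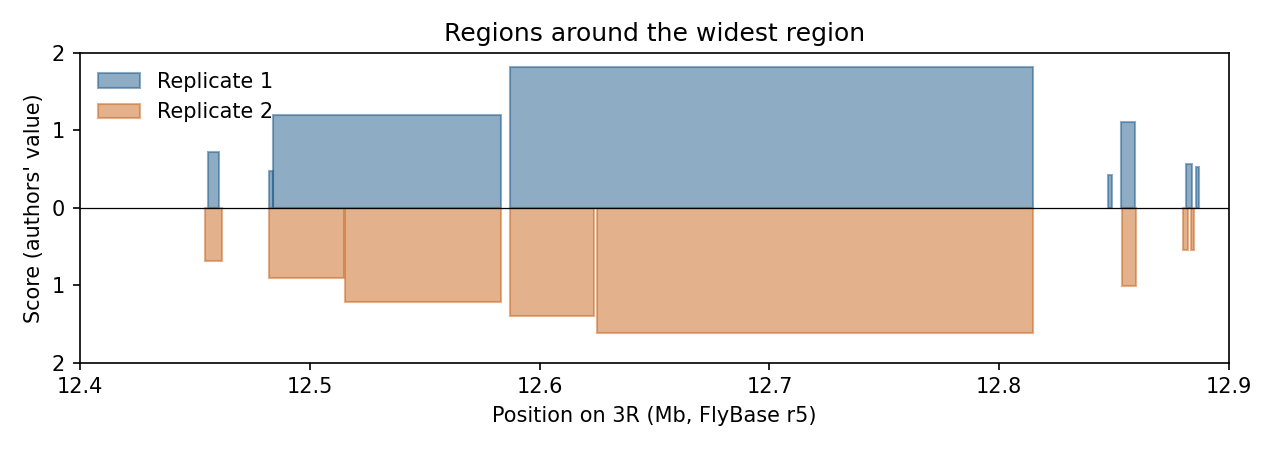
Polycomb-enriched regions around the widest region on 3R (x axis, Mb of FlyBase r5), with replicate 1 drawn upward and replicate 2 downward; bar width is region width and bar height is the score. The outer borders and the gap between the broad replicate 1 regions lie at similar positions in both libraries, and replicate 2 splits each of these regions.

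The other wide regions were spread over 2L, 2R, 3L and X, and replicate 2 covered each to at least 89.8%. On 2R a region from 7352214 to 7465881 measured 113.7 kb in replicate 1, and replicate 2 covered 99.6% of it with 3 regions. On 2L a region from 5371333 to 5477686 measured 106.4 kb and was covered to 94.0%, and another from 3530376 to 3620950 measured 90.6 kb and was covered to 97.7%. On 3L a neighbouring pair, from 12556573 to 12639054 (82.5 kb) and from 12639114 to 12725289 (86.2 kb), was covered to 98.2% and 99.3%. The X region from 5423005 to 5506106 (83.1 kb) was the most divided, with 10 replicate 2 regions covering 89.8% of it.

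The highest Polycomb score among regions found in both lists belonged to a narrow region near the right end of 3R, from 27893573 to 27899780 (6.21 kb). It scored 3.05 in replicate 1 and 2.85 in replicate 2. Next came a 32.6 kb region of X from 2010621 to 2043178, with scores of 2.56 and 2.53. A 98.5 kb region of 2R from 8833361 to 8931867 scored 2.14 and 2.43, and an 8.31 kb region near the left end of 2L, from 5038 to 13342, scored 1.99 and 2.10. The remaining 6 of the 10 highest were 2R 5859712 to 5877334 (1.89 and 1.73), 3L 8992206 to 9040434 (1.88 and 2.03), 2L 3656968 to 3668741 (1.85 and 1.49), 3R 647472 to 702049 (1.83 and 1.94), X 17645899 to 17687994 (1.82 and 1.59), and the widest 3R region named above. Among these 10 regions, the lowest share of bases covered by replicate 2 was 90.0%, in the 2L region near the arm end. The scale of the score is not given in the sources used here.

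Where 1 region of each list formed a pair, a high Polycomb score in one library went with a high score in the other. Across the 385 pairs in which 1 region of each list overlapped only the other, Spearman's rho was 0.83 and Pearson's r was 0.94 (permutation p = 1e-05 for both, two-sided, the smallest that 100000 permutations can give). Regions are not independent replicates, so these values describe the 2 lists. The rank correlation was 0.92 in the 72 pairs of 10 kb or more in replicate 1 and 0.40 in the 111 pairs under 2 kb, a split chosen after the values were seen, and the difference between these correlations was not tested. By Pearson's r the gap was smaller, with 0.93 and 0.70 in the same pairs. Over all 1027 overlapping pairs, where a broad region is paired with each of its fragments, rho was 0.57.

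**Figure D4:**
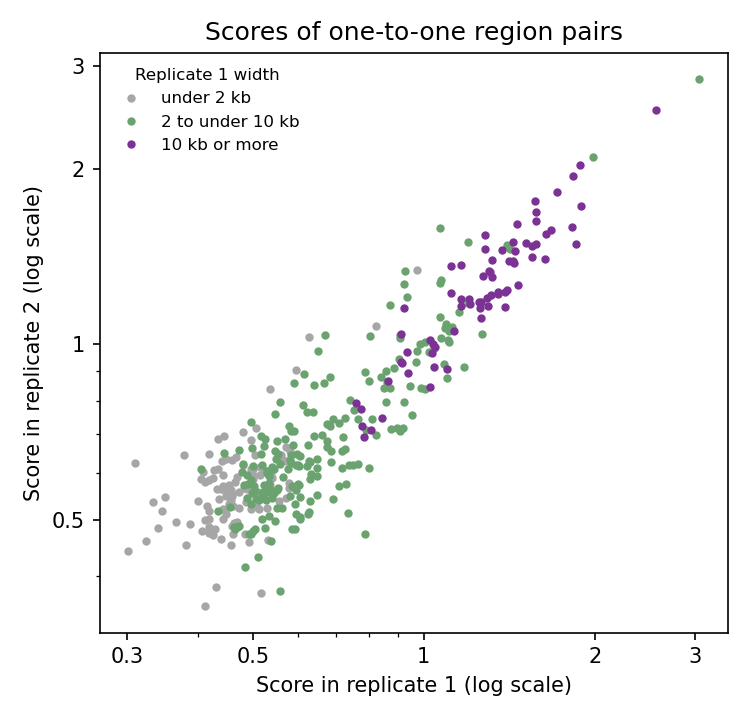
Score in replicate 1 (x axis, log scale) against score in replicate 2 (y axis, log scale) for the 385 one-to-one pairs, coloured by replicate 1 width. Pairs of 10 kb or more follow a narrow diagonal (rho 0.92, Pearson's r 0.93), and pairs under 2 kb scatter more widely (rho 0.40, Pearson's r 0.70).

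Regions found in one list only were narrower than the shared ones and, over all widths, had lower scores. The 420 such regions of replicate 1 had a median width of 1526.5 bases and a median score of 0.482, against 4026 bases and 0.616 for the 769 shared regions. In replicate 2 the 552 single-list regions had medians of 1512 bases and 0.550, against 3355 bases and 0.657 for the 853 shared ones. Within the replicate 1 list, the median rank of the shared regions was higher by 37.0 percentiles for score and 41.7 percentiles for width. In replicate 2 it was higher by 28.9 and 43.3 percentiles (two-sided permutation p = 1e-05 for each of the 4 differences). The permutations did not allow for wide regions being overlapped more often by chance. Circular shifts gave mean shares of 21.8% and 18.8% for regions of 10 kb or more, against 8.53% and 8.20% under 2 kb. Unrelated lists could thus give differences in the same direction, of a size not estimated here. Within width classes, a choice made after the values were seen, the score difference was smaller. From 2 kb to under 10 kb it was 13.6 percentiles in replicate 1 (permutation p = 0.00013) and 8.68 in replicate 2 (permutation p = 0.0294). Width still varied inside this class. In replicate 1, 66 of 316 regions from 2 to under 5 kb were single-list, against 3 of 131 from 5 to under 10 kb. In replicate 2 the counts were 73 of 369 and 1 of 126. Wider regions scored higher, so the score difference in this class can come from width. Under 2 kb no difference was called, with -0.883 and -2.31 percentiles (permutation p = 0.737 and 0.401). The widest single-list region of replicate 1 was 7.15 kb on X, from 13886432 to 13893585, 135.9 kb from any replicate 2 region. That of replicate 2 was 5.27 kb on 2R, from 4544706 to 4549971, 5.40 kb from the nearest replicate 1 region. Both were picked out after the values were seen.

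The highest scores among single-list regions lay on U, the unplaced scaffolds of the assembly, and on X. The 5 highest single-list regions of replicate 2 were all on U, from 3143516 to 3144992 (score 2.55), 5457743 to 5459716 (2.31), 8067734 to 8069659 (2.26), 8466502 to 8468964 (2.96) and 9745326 to 9747641 (2.46). In replicate 1, 4 of the 5 were on U, led by 6438855 to 6440210 (2.39) and 8383092 to 8384957 (2.17), followed by 6688036 to 6689924 (1.07) and 9350068 to 9351930 (0.939). The other one was on X, from 21772783 to 21774405 (1.77), 524.7 kb from the nearest replicate 2 region. On X, 2L, 2R, 3L and 3R, X held 14 of the 20 highest single-list regions of replicate 1 and 13 of the 20 highest of replicate 2, against 78 of 412 and 92 of 536 single-list regions of any score, a count made after the values were seen. Of the U regions, 1 of 7 in replicate 1 and 1 of 13 in replicate 2 was found in the other list.

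Every chromosome arm carried Polycomb regions. They covered 9.19% of 3R in replicate 1 and 9.14% in replicate 2, 7.33% and 7.23% of 2L, 7.15% and 6.85% of X, 5.76% and 5.92% of 2R, and 5.39% and 5.68% of 3L. The small, mostly heterochromatic chromosome 4 had the highest covered share, 15.0% and 16.5%, in 18 regions per library. Dealing blocks of regions under 50 kb apart to the arms at random in proportion to length, a test added after the values were seen, called none of the 6 arms in either library (two-sided permutation p before adjustment at least 0.178 in replicate 1 and 0.169 in replicate 2; lowest Benjamini-Hochberg adjusted values 0.532 and 0.563). For the short chromosome 4 the limits of the dealt shares were 0.102% and 27.2% in replicate 1, and 0.118% and 27.1% in replicate 2. Shares of 15.0% and 16.5% could therefore not be called there, and whether chromosome 4 stands out stays undecided. Region counts over the 8 sequences that held any region departed from sequence length (chi-square 123 in replicate 1 and 128 in replicate 2, simulated p = 1e-05 for both). Sparse regions on U and on the heterochromatic sequence 3LHet made up 95.4 and 106.8 of these values, with 9 and 14 regions where length alone gave 112.7 and 133.2. On X, 2L, 2R, 3L and 3R alone, the chi-square was 14.7 in replicate 1 (simulated p = 0.0052) and 8.61 in replicate 2 (simulated p = 0.0711). The simulated draws treated each region as independent, although regions lay in groups, so p-values from region counts can be too small. With regions under 50 kb apart counted as 1 block on these 5 arms, the chi-square was 4.44 and 2.42 (simulated p = 0.35 and 0.66). This was also a choice made after the values were seen. The remaining 6 of the 14 sequences in the file headers held no region and did not enter the chi-square.

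Polycomb regions lay in groups along the arms. The median distance from a region to its nearest neighbour in the same list was 1.57 kb in replicate 1 and 2.11 kb in replicate 2. Regions of the same widths placed at random had medians of 28.6 kb and 24.4 kb, and the lowest of 10000 placements gave 22.4 kb and 19.6 kb (one-sided permutation p = 0.0001 for both, the smallest these placements can give). The lists held 301 gaps under 1 kb in replicate 1 and 295 in replicate 2. With such neighbours merged, the medians were 5.21 kb and 5.77 kb, against 38.7 kb and 31.2 kb at random (one-sided permutation p = 0.0001 for both). In the upper 50% of each list by score they were 3.75 kb and 5.01 kb, against 56.8 kb and 47.8 kb.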

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

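Tests on blocks and by width class were chosen after the values were seen. Under the alternatives set beforehand, 37 tested values kept their direction and their side of the threshold and 1 lost its call, while 4 region counts stayed within 1.5 times and 2 moved further. The call lost was the departure of region counts from arm length in replicate 2, where the chi-square was 8.61 on X, 2L, 2R, 3L and 3R alone (simulated p = 0.0711). Keeping the upper 50% of each list by score left 595 and 703 regions by construction. The share of replicate 1 regions found in replicate 2 ranged from 43.5% (50% of both regions) to 73.8% (upper 50% by score), and the Jaccard index from 71.3% to 78.0%. Arm counts were repeated on blocks of regions under 50 kb apart on the 5 large arms, and the chi-square was 4.44 in replicate 1 and 2.42 in replicate 2 (simulated p = 0.35 and 0.66). Fewer, more widely spaced units enter that test. Under the alternatives added later, 10 values kept their direction and call and 6 lost the call, 3 of them with the opposite sign, and 0 were called in the opposite direction. Among regions under 2 kb, the shared minus single-list difference in median score rank was -0.883 percentiles in replicate 1 and -2.31 in replicate 2 (permutation p = 0.737 and 0.401), against 37.0 and 28.9 over all widths. The X minus autosome difference in median score was 0.0829 in replicate 1 and 0.121 in replicate 2 for all regions. For regions of 10 kb or more it lost its call in replicate 1 (0.0788, permutation p = 0.275) and was -0.00789 in replicate 2 (permutation p = 0.918). Technical causes are weighed below, and no biological cause was tested. No paired analysis was possible because the input libraries have no values here, so ChIP and input of the same number could not be set against each other. Leaving out a replicate gives no overlap, and the other results are given per library. The planned placement relative to genes, gene lists and motifs were not run. Depth was unknown, so the lists cannot show whether a region missing from one of them was unenriched there or under the threshold.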

Other observations

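The tests of arm ends, of unplaced sequence and of unrelated positions were chosen after their results were seen. The tests of nearness, of score among narrow regions and of the X chromosome were written before theirs, for patterns noticed in the same data, and the bootstrap criterion for X was added after the values of that test had been seen. Without that criterion the X test was counted in favour of a higher score needed to be called, and with it that explanation is undecided. In replicate 1 the X median at 10 kb or more lay 0.0788 above the autosome median (permutation p = 0.275). The prediction, no X excess in such regions, was therefore not met there by sign.

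Polycomb regions stood at 3 of the 5 outer (telomeric) ends of the large chromosome arms. On 3R, the highest-scoring region on the arms in both lists lay 5.27 kb and 5.31 kb from the right end. On 2L, a region 5.04 kb and 5.06 kb from the left end ranked 6 in replicate 1 and 9 in replicate 2 by score, and on 2R the outermost region lay 10.5 kb and 10.4 kb from the right end. Within 25 kb of that 2R end the highest scores were lower, 0.927 in replicate 1 (rank 216) and 0.975 in replicate 2 (rank 203). The left ends of 3L and X and all 5 inner (centromeric) ends had no shared region within 25 kb, and the first shared regions lay 367.0 kb from the left end of 3L and 439.7 kb from that of X. Sets of 1 random position per arm had a mean of 0.661 positions with such a region (10000 sets, one-sided permutation p = 0.0182), but the pattern and the 25 kb window were chosen from the same 5 ends, so whether outer ends are Polycomb regions more often than other positions stays open.

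Regions called in only 1 library lay within 5 kb of the other list more often than under circular shifts (47.1% in replicate 1 and 31.2% in replicate 2, against at most 12.9% and 9.29%), although most, 222 of 420 and 380 of 552, lay 5 kb or more away. The shares under shifts were not taken over these same 420 and 552 regions, so the comparison is approximate. Positions unrelated to the other library are argued against as the whole cause, and stay open for a part of these regions. Differently drawn edges and fragments of blocks may account for those within 5 kb, although separate sites could lie as near. Weak sites near the calling limit stay open, since under 2 kb the shared regions did not score detectably higher than the single-list ones (shared minus single-list median score -0.00251, bootstrap 95% interval -0.0136 to 0.0132, permutation p = 0.729 in replicate 1; -0.00625, -0.0235 to 0.00756, permutation p = 0.332 in replicate 2). From 2 kb to under 10 kb, shared regions did rank higher in score, by 13.6 percentiles in replicate 1 (permutation p = 0.00013) and 8.68 in replicate 2 (permutation p = 0.0294). Width was not held constant inside that class, so this difference can come from width and does not bear on the calling limit. No biological explanation was tested.

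Polycomb regions on X scored higher than those on 2L, 2R, 3L and 3R, with medians of 0.607 against 0.524 in replicate 1 and 0.696 against 0.575 in replicate 2 (two-sided permutation p = 1e-05 for both, the smallest possible). A different mix of widths is argued against as the whole cause, since the difference within width quintiles was 0.0481 in replicate 1 (permutation p = 0.00205) and 0.0916 in replicate 2 (permutation p = 1e-05). These permutations treated regions as independent, although regions lay in groups, so the p-values can be too small. Scores on X were not compared by block. Embryos with a single X give fewer reads on X, so a higher score might be needed to be called there. That was predicted to raise narrow regions and not broad ones. The calling rule and the scale of the score are not known, so the prediction rests on an assumption. The difference was 0.0725 and 0.102 under 2 kb, as large from 2 kb to under 10 kb at 0.0974 (bootstrap 95% interval 0.0555 to 0.125) and 0.103 (0.0808 to 0.128), and 0.0788 (-0.146 to 0.164) and -0.00789 (-0.167 to 0.131) at 10 kb or more, where the intervals are too wide to decide. No biological explanation was tested.

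Scores on unplaced sequence were high, with a median of 1.07 in replicate 1 and 1.82 in replicate 2, against 0.496 and 0.557 for arm regions of 1300 to under 3500 bases. Reads of repeated sequence collected on these scaffolds may be the source, which stays open. U regions were found in the other list in 1 of 7 and 1 of 13 cases, against 47.0% and 45.0% of those arm regions (Fisher's exact two-sided p = 0.129 and 0.00872). The 7 regions of replicate 1 are too few to decide, and the repeat content of the scaffolds was not measured. No biological explanation was tested.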
